A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 12 samples.

How the data were processed

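Total RNA was measured by RNA sequencing in 12 libraries of the cyanobacterium Synechococcus elongatus, in 4 groups of 3: wild type (WT), a strain that overexpresses kaiA from a zinc-induced promoter (kaiA-Ex), a labA knock-out (labA-KO) and a strain with both changes (kaiA-Ex/labA-KO). Per the labels' protocols, RNA was treated with DNase and depleted of ribosomal RNA with a kit for bacteria. Per the submitters' processing notes, the tools were Trim Galore 0.6.10, SAMtools 1.11.0, StringTie 2.1.7, DESeq and DESeq2 1.36.0. The aligner, genome build, annotation and strand setting are not given in the sources used here.

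The values are estimated counts deposited by the authors, not normalised for depth, with 1 row per locus tag or assembled transcript. They were whole numbers, but each library had between 47 and 58 rows at 1 and between 0 and 4 rows at 0, a pattern of estimates rounded up. They were used as deposited, and because the number of reads behind 1 estimated count is unknown, counting intervals cover counting error only and are approximate. The planned test assumed plain counts; the same test was kept for these whole numbers.

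The table held 2769 rows: 2712 gene rows, 55 RNA-feature rows and 2 assembled transcripts without a locus tag. The reference table of gene names used here is for assembly GCF_030544905.1, and 0 of the IDs matched it. The files do not pair the IDs with names either, so features are given by their IDs. The planned lists of pathway genes, and the levels of kaiA and labA as a check of the strain labels, were therefore not analysed here. Antisense or overlapping features and near-identical copies cannot be told apart in these counts without the strand and multi-mapping settings.

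Libraries were assigned to groups from the sample titles, and table columns to libraries by strain and replicate number in the column names. Totals per library ran from 57874489 to 92072094 estimated counts. Rows with too few counts were removed by filterByExpr, which left 2673 rows for testing and took out 96. Libraries were scaled by the trimmed mean of M values (TMM). Differences were tested with edgeR 4.0.16 in R 4.3.3, by a robust quasi-likelihood fit over all 12 libraries with group means and no block. P-values were adjusted by Benjamini-Hochberg, and a feature was called at an adjusted p under 0.05. Standard errors (SE) of log2 fold changes were taken as the absolute change divided by the square root of F. The contrasts were the 5 pairwise ones given in the report and the interaction, which is the kaiA-Ex/labA-KO minus kaiA-Ex difference less the labA-KO minus WT difference.

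The rule for named features was fixed before the data were examined. It took the largest rises and falls among called features with a mean of at least 10 CPM (counts scaled to a common library size), with CPM that did not overlap between the 2 groups. The interaction had no such overlap condition, and its mean was over all 12 libraries. The rule also asked for a gene symbol or product, which could not be applied. It took more features per direction than are named here, where at most 2 rises and 2 falls per contrast are given. The named kai and lab genes and the list members of the rule were not analysed here.

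Agreement between contrasts was the correlation of log2 fold changes across features. For contrasts that share the WT libraries, 20 sets of unchanged groups were simulated beside it. Runs were defined as at least 5 neighbouring rows, with locus tag numbers 5 apart, called in the same direction, and were set against 1000 shuffles of the calls. The model was tested on simulated data with 200 changed features. At a simulated 2-fold change it recovered 94% of them for kaiA-Ex vs WT, with 3.09% false calls, among 2671 features. For the interaction at 2-fold it recovered 89%, with 7.29% false calls, among 2671 features. Most features were unchanged in these simulations, while 611 to 1661 were called per pairwise contrast in the data. These rates may therefore not hold for the data.

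Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom with limma 3.58.1, only the libraries compared, the replicate number as a block, RNA-feature rows left out, a fold threshold, a stricter adjusted p, and each library left out in turn. Further alternatives were added after the data were seen: libraries thinned to the lowest total, an outlying pair of libraries left out, features with a range over 20-fold within a group left out, and the rows listed first left out. The runs and the rows listed first were also chosen for description after the data were seen. In kaiA-Ex/labA-KO vs labA-KO, the deviations of all 3 same-numbered pairs from their group means correlated over 0.1, from 0.15 to 0.18, so the replicate numbers of the labels were taken to pair these libraries, and a block fit of these 6 libraries was added after the data were seen. The labels do not say what a number shares. Differently numbered libraries could correlate more, at 0.53 for kaiA-Ex replicate 2 with kaiA-Ex/labA-KO replicate 1, so this pairing is not established. Libraries of the same group were checked for duplicates, and the smallest chi-square per degree of freedom within a group was 67.6, so no pair agreed within sampling noise.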

Results

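The series addressed whether changing the genes labA and kaiA can raise the output of bioproducts in the cyanobacterium Synechococcus elongatus. KaiA is a core protein of the cyanobacterial circadian clock that promotes phosphorylation of KaiC, and LabA is a protein known for its part in the feedback of KaiC on gene expression. Transcript levels were measured in 4 strains with 3 libraries each. Cells grew for 3 days in constant light at 30 °C, under about 40 µE, on plates. They then had 12 h of darkness and were collected after 12 h of light. Both strains with kaiA overexpression were given 10 µM ZnCl2 and the others were not, so zinc and kaiA overexpression cannot be separated in these comparisons. Each group was a single strain, so other differences between the strains cannot be separated from the named changes either. The labels do not state that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

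Library totals ranged from 68009226 to 92072094 estimated counts in WT, 83295511 to 87786154 in kaiA-Ex, 57874489 to 81131314 in labA-KO and 60790171 to 67067139 in kaiA-Ex/labA-KO. RNA-feature rows took 13.8% ± 0.554 of counts in WT, 12.5% ± 1.29 in kaiA-Ex, 16.9% ± 1.16 in labA-KO and 15.7% ± 1.89 in kaiA-Ex/labA-KO (SD, n = 3). The first principal component of log2 CPM held 40.1% of the variance and separated both labA-KO groups from WT and kaiA-Ex. The second held 20.1%, with WT and kaiA-Ex at opposite ends. Replicate libraries correlated at 0.964 to 0.987 across features, and libraries of different groups at 0.908 to 0.979. No feature had at most 5 counts in all libraries of both labA-KO groups and at least 100 in all others. Among features with at least 100 counts in all others, the lowest CPM there was at most 9.76 times the highest in the labA-KO groups. By this measure the knock-out was not visible as a lost transcript, and the strain labels were taken as given.

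**Figure D1:**
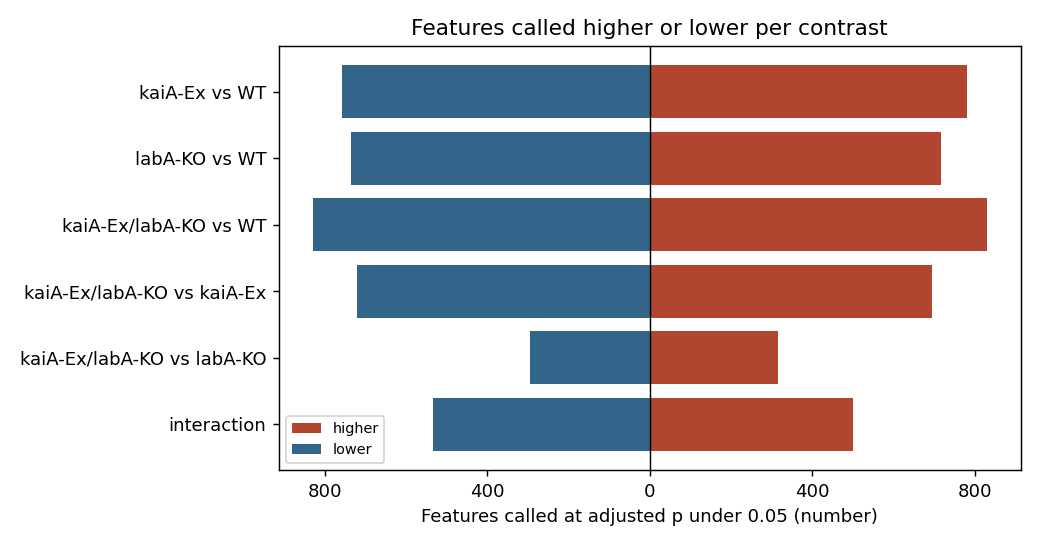
Number of features called higher (right) or lower (left) at adjusted p under 0.05 in each of the 6 contrasts, from edgeR's quasi-likelihood test. The bars for kaiA-Ex/labA-KO vs labA-KO, 316 higher and 295 lower, are the shortest.

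The effect of kaiA overexpression with zinc in the wild-type background was asked first. In kaiA-Ex, 782 features rose and 759 fell against WT, of 2673 tested. Among features changed at least 2-fold, rises outnumbered falls, with 160 against 31. gene-SYNPCC7942_RS00170 rose from 6.52 ± 0.964 to 111.2 ± 15.1 CPM (SD, n = 3), a log2 change of 4.09 (SE 0.26). gene-SYNPCC7942_RS10340 rose from 17.7 ± 1.49 to 270.6 ± 21.3 CPM, a log2 change of 3.93 (SE 0.11). gene-SYNPCC7942_RS13970 fell from 1713 ± 44.2 to 469.6 ± 36.2 CPM, and gene-SYNPCC7942_RS08765 from 223.2 ± 5.61 to 69.0 ± 3.70 CPM, with log2 changes of -1.87 (SE 0.09) and -1.69 (SE 0.06). The adjusted p of these features in edgeR's quasi-likelihood test ran from 1.07e-09 for gene-SYNPCC7942_RS10340 to 3.20e-07 for gene-SYNPCC7942_RS00170. CPM of the 2 groups did not overlap for 67.2% of features, against 10% by chance.

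Some neighbouring features changed together in kaiA-Ex, where 12.3% of the calls lay in runs. The share was 10.8% for labA-KO vs WT, 11.8% for kaiA-Ex/labA-KO vs WT and 13.1% for kaiA-Ex/labA-KO vs kaiA-Ex. It was 7.8% for the interaction and 2.6% for kaiA-Ex/labA-KO vs labA-KO. In kaiA-Ex vs WT 190 called features lay in 29 runs of at least 5 neighbours, against a mean of 28.3 features in shuffled calls (one-sided permutation p = 0.001, the smallest that the permutations can give). At an adjusted p under 0.01 in edgeR's test 126 features lay in runs, and with a fold threshold of log2 1 there were 0. The longest run held 15 features, all lower, with a mean log2 change of -0.66. It was not particular to kaiA-Ex. The same 15 rows were lower in labA-KO vs WT, at a mean of -0.78. In kaiA-Ex/labA-KO vs WT 14 of them formed a lower run, at -0.87, and these contrasts share the WT libraries. The 55 rows listed first in the table rose nearly as a group, with 47 of 52 tested members higher and 0 lower, and a median log2 change of 1.13. Their share of counts was 0.692% ± 0.0528 in kaiA-Ex and 0.245% ± 0.0125 in WT (SD, n = 3).

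The effect of the labA knock-out without zinc was asked next. In labA-KO, 717 features rose and 735 fell against WT, with 125 rises and 60 falls of at least 2-fold. gene-SYNPCC7942_RS14000 rose from 4.09 ± 0.375 to 1545 ± 81.8 CPM (SD, n = 3), and gene-SYNPCC7942_RS13995 from 3.95 ± 0.253 to 1157 ± 65.9 CPM. Their log2 changes were 8.56 (SE 0.25) and 8.20 (SE 0.09). gene-SYNPCC7942_RS08200 fell from 3374 ± 186.4 to 258.1 ± 12.1 CPM, and gene-SYNPCC7942_RS04415 from 120.8 ± 7.33 to 23.5 ± 1.23 CPM. Their log2 changes were -3.71 (SE 0.08) and -2.36 (SE 0.12). The adjusted p in edgeR's quasi-likelihood test was at most 1.03e-07, that of gene-SYNPCC7942_RS04415. Of the called features, 157 lay in 24 runs, against 20.8 in shuffled calls (one-sided permutation p = 0.001, the smallest that the permutations can give). Without labA-KO replicate 2, 99 features lay in runs, 80 did at an adjusted p under 0.01 in edgeR's test, and 11 did with a fold threshold of log2 1. The rows listed first were mostly lower, with 35 lower and 8 higher and a median log2 change of -0.67. Their summed share of counts was 0.232% ± 0.00689 in labA-KO against 0.245% ± 0.0125 in WT (SD, n = 3), and the libraries of these groups overlapped in it.

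The strain with both changes was also compared with WT. In kaiA-Ex/labA-KO, 830 features rose and 831 fell, with 184 rises and 98 falls of at least 2-fold. gene-SYNPCC7942_RS14000 reached 6361 ± 1743 CPM and gene-SYNPCC7942_RS13995 reached 4141 ± 215.6 CPM (SD, n = 3), with log2 changes of 10.60 (SE 0.27) and 10.04 (SE 0.10) against WT. gene-SYNPCC7942_RS08200 was at 244.8 ± 21.0 CPM and gene-SYNPCC7942_RS04415 at 19.9 ± 4.05 CPM, with log2 changes of -3.79 (SE 0.08) and -2.61 (SE 0.12). The adjusted p in edgeR's quasi-likelihood test was at most 3.33e-08, that of gene-SYNPCC7942_RS04415. With upper-quartile factors 628 features were higher and 1026 lower, and with library totals only 647 and 963, so the balance of directions depended on the scaling.

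The labA knock-out was then compared between strains that both overexpressed kaiA and both received zinc. In kaiA-Ex/labA-KO, 695 features were higher and 722 lower than in kaiA-Ex. gene-SYNPCC7942_RS14000 and gene-SYNPCC7942_RS13995 again led the rises, with log2 changes of 8.99 (SE 0.25) and 8.68 (SE 0.10). gene-SYNPCC7942_RS11720 was at 290.4 ± 41.4 CPM in kaiA-Ex and 9.05 ± 1.85 CPM in the strain with both changes, and gene-SYNPCC7942_RS11725 at 526.1 ± 82.2 and 39.3 ± 12.8 CPM (SD, n = 3). Their log2 changes were -5.00 (SE 0.17) and -3.74 (SE 0.20), with adjusted p of 2.71e-09 and 1.06e-07 in edgeR's quasi-likelihood test. Both features had risen in kaiA-Ex vs WT, by log2 changes of 3.32 (SE 0.16) and 3.54 (SE 0.20). In labA-KO vs WT, without zinc, their log2 changes were only -1.65 (SE 0.15) and -0.62 (SE 0.19). The rows listed first were lower, with 44 of 52 called lower and a median log2 change of -1.81. Their share of counts was 0.246% ± 0.0200 in kaiA-Ex/labA-KO (SD, n = 3), against 0.692% ± 0.0528 in kaiA-Ex. Rises made up 49.0% of the calls, and 33.5% with library totals only.

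**Figure D2:**
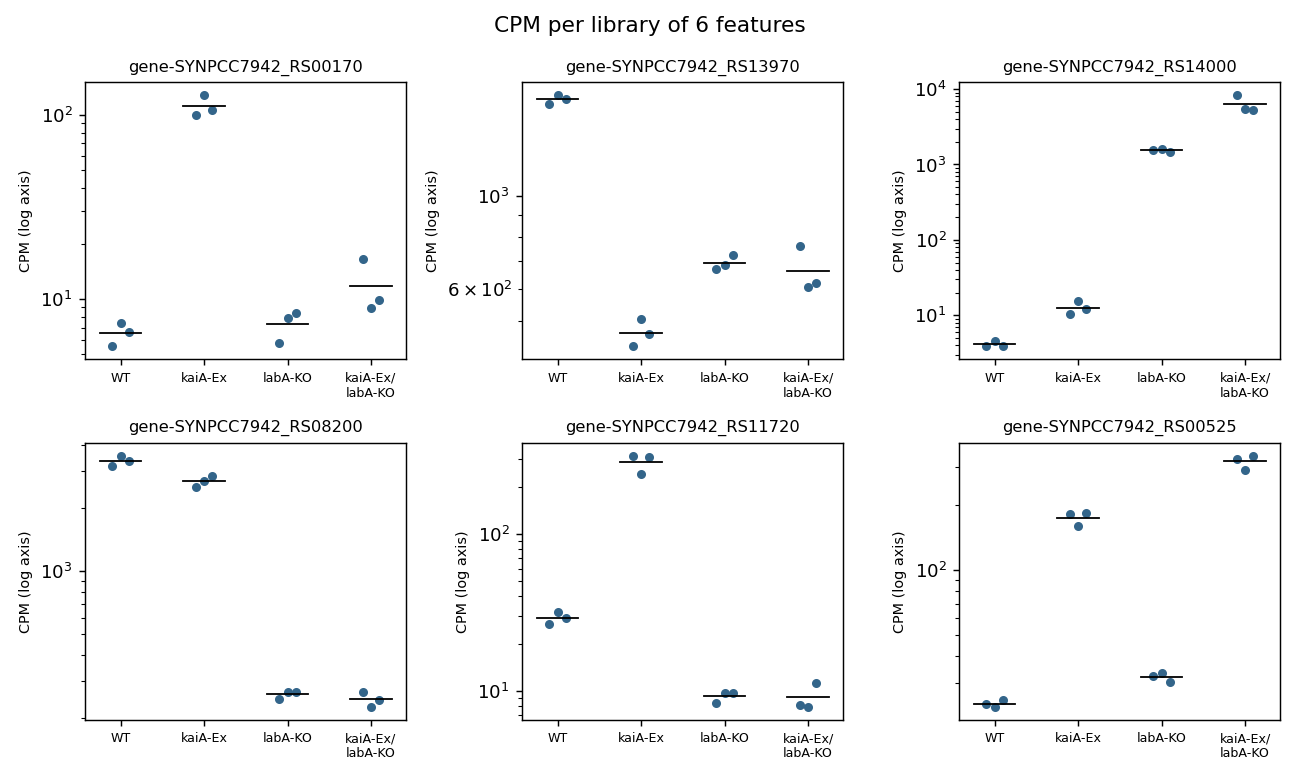
CPM on a log axis in each library (points) and the group mean (line) for 6 features, by strain, with 3 libraries per strain. gene-SYNPCC7942_RS14000 lies near 4.09 CPM in WT and at 1545 and 6361 CPM in labA-KO and kaiA-Ex/labA-KO, and gene-SYNPCC7942_RS11720 stands at 290.4 CPM in kaiA-Ex.

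The effect of kaiA overexpression with zinc was also measured in the labA-KO background. Here 316 features were higher and 295 lower, and 19 rose and 7 fell at least 2-fold. gene-SYNPCC7942_RS00525 rose from 32.1 ± 1.45 to 320.3 ± 25.2 CPM, and gene-SYNPCC7942_RS00530 from 76.8 ± 2.88 to 457.9 ± 65.6 CPM (SD, n = 3). Their log2 changes were 3.32 (SE 0.08) and 2.58 (SE 0.09). gene-SYNPCC7942_RS08765 fell by 1.19 (SE 0.06) on the log2 scale, and gene-SYNPCC7942_RS05255 fell by 1.17 (SE 0.27). The adjusted p in edgeR's quasi-likelihood test was at most 4.45e-07 for the others, and 0.0118 for gene-SYNPCC7942_RS05255. With only the 6 libraries compared in the fit, 313 features were called in place of 611, with the replicate block added to that fit 283 were, and 314 were at an adjusted p under 0.01 in the fit of all libraries. Rises made up 51.7% of the calls, 32.2% with upper-quartile factors and 23.8% with library totals only, so the balance of directions depended on the scaling.

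Whether the knock-out changes differed with kaiA overexpression was tested by the interaction. It was called for 1035 features, 500 positive and 535 negative. Of those beyond 2-fold, 110 were negative and 33 positive. gene-SYNPCC7942_RS13190 was at 61.6 ± 2.12 CPM in WT, 720.6 ± 34.3 in kaiA-Ex, 63.0 ± 2.80 in labA-KO and 64.9 ± 6.34 in kaiA-Ex/labA-KO (SD, n = 3), and its interaction was -3.50 (SE 0.10) on the log2 scale. gene-SYNPCC7942_RS00170 had an interaction of -3.41 (SE 0.33) and gene-SYNPCC7942_RS13970 one of 1.80 (SE 0.12). gene-SYNPCC7942_RS13855 had the largest positive value by the rule, 6.90 (SE 1.80), but its CPM within kaiA-Ex/labA-KO ranged from 0.458 to 111.0, and the value was 5.15 without kaiA-Ex/labA-KO replicate 1. The adjusted p in edgeR's quasi-likelihood test was 0.0119 for gene-SYNPCC7942_RS13855. Over the 25 alternatives that gave a value for it, the adjusted p ran from 5.82e-05, in edgeR's test without kaiA-Ex/labA-KO replicate 2, to 0.672 with limma-voom. The rows listed first had 43 of 52 members called negative, with a median of -1.20. Positive values made up 48.3% of the calls, and 29.7% with library totals only, which moved the median interaction of all features to -0.13.

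The same modification was compared between backgrounds that share no library. For the labA knock-out, log2 fold changes without and with kaiA overexpression correlated at r = 0.60 across 2673 features (Spearman 0.49); features are not independent replicates. Both contrasts called 411 features higher and 365 lower, where independent lists would share 186.4 and 198.5, and 151 went opposite ways. For kaiA overexpression with zinc, without and with the knock-out, r was 0.36 (Spearman 0.40). Both called 241 higher and 158 lower, where independent lists would share 92.4 and 83.8, and 55 went opposite ways. Without kaiA-Ex replicate 2 that r was 0.18 and the Spearman value 0.32.

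**Figure D3:**
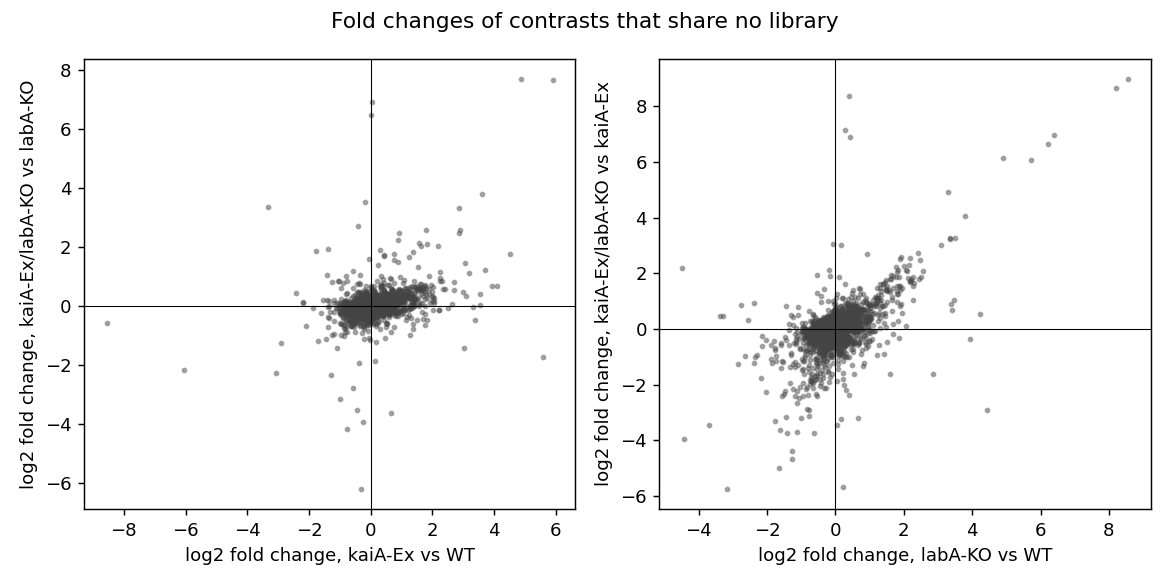
Log2 fold changes of each of the 2673 features in contrasts that share no library: kaiA overexpression with zinc (left) and the labA knock-out (right), each in both backgrounds. The right panel has r = 0.60 and the left panel r = 0.36.

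Contrasts that share the WT libraries correlate even with no effect, so simulated unchanged groups were set beside them, with the overlap that independent lists would have. The simulated r follows from the sharing itself and not from the size of the changes. A real r near or below it therefore does not mean that there is no common change. The labA-KO and kaiA-Ex/labA-KO changes against WT had r = 0.83, with 0.48 in simulated unchanged groups, and a covariance of 0.532 against 0.0395. Both called 596 features higher and 630 lower, where independent lists would share 222.6 and 228.5. The kaiA-Ex and kaiA-Ex/labA-KO changes had r = 0.50 against 0.48, and a covariance of 0.308 against 0.0396. Both called 479 higher and 512 lower, where independent lists would share 242.8 and 236.0. The kaiA-Ex and labA-KO changes had r = 0.38 against 0.49, and a covariance of 0.183 against 0.0397. Both called 361 higher and 434 lower, where independent lists would share 209.8 and 208.7. Part of these excesses may come from the shared controls.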

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

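The patterns weighed here were noticed in the data first, and the thinning of the libraries and the tests on the rows listed first were chosen only after that, as were the alternatives for interactions of features named in other contrasts. What drew attention to each result is that the effect of a change differed between backgrounds by the interaction test. This held for 1035 features. Of 100 splits of the 12 libraries into groups of the same sizes, 1, the real one, gave as many features and the highest other gave 477. The other splits also mix strains that differ from each other, which adds to the spread in the fit, so they do not decide whether that number can come by chance. A difference private to a strain would give an interaction as well, such as the possible lost locus in kaiA-Ex described below. For each pairwise contrast 10 splits exist, too few for a share under 0.05, and 1 of 10, the real grouping, gave the largest number: 1541 for kaiA-Ex vs WT, 1452 for labA-KO vs WT, 1661 for kaiA-Ex/labA-KO vs WT, 1417 for kaiA-Ex/labA-KO vs kaiA-Ex and 611 for kaiA-Ex/labA-KO vs labA-KO. The highest other split gave 1 feature, and 0 for labA-KO vs WT. These other splits mix the strains within groups too, which adds to the spread, so their low numbers do not measure chance. For kaiA-Ex/labA-KO vs labA-KO the replicate numbers were taken to pair the libraries. There, the 3 other splits that part as many pairs gave 0 features, and the 6 that part fewer gave at most 1, with the same limit.

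Among named features, only those with a called interaction are listed here. The interactions of gene-SYNPCC7942_RS14000 (0.43) and gene-SYNPCC7942_RS08200 (0.25) were not called, with adjusted p of 0.246 and 0.0774 in edgeR's quasi-likelihood test. gene-SYNPCC7942_RS00170, gene-SYNPCC7942_RS13970, gene-SYNPCC7942_RS13190 and gene-SYNPCC7942_RS13855 were picked by the size of the interaction itself. The interaction on the log2 scale was -3.41 for gene-SYNPCC7942_RS00170, -3.24 for gene-SYNPCC7942_RS10340, -3.35 for gene-SYNPCC7942_RS11720, -3.12 for gene-SYNPCC7942_RS11725, -3.50 for gene-SYNPCC7942_RS13190 and -1.14 for gene-SYNPCC7942_RS05255. With each of the 12 libraries left out in turn the last lost its call in 10 cases, all but those of WT replicate 1 and kaiA-Ex replicate 2, and its value ran from -1.57 without WT replicate 1 to -0.91 without kaiA-Ex replicate 3. It was 1.80 for gene-SYNPCC7942_RS13970, 1.361 for gene-SYNPCC7942_RS04415, 0.50 for gene-SYNPCC7942_RS08765, 0.48 for gene-SYNPCC7942_RS13995, 0.46 for gene-SYNPCC7942_RS00525 and 0.79 for gene-SYNPCC7942_RS00530. For gene-SYNPCC7942_RS13855 it was 6.90, but 5.15 without kaiA-Ex/labA-KO replicate 1 and 7.48 without kaiA-Ex/labA-KO replicate 2, the lowest and highest values with a library left out. For gene-SYNPCC7942_RS06270, which had 2 to 3 counts in each kaiA-Ex library, the fitted value was 7.98.

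The rows listed first in the table moved as a group, with a median interaction of -1.20. In kaiA-Ex vs WT the smallest median of these rows over the other scalings was 1.09, so the choice among those scalings does not account for it. Those scalings moved the median of all features only from 0.002 to values between -0.040 and 0.028. A median of these rows near 0 was therefore out of reach, and the test decides no more than that. A common change in gene dosage stays open for kaiA-Ex vs WT, where 47 of 52 tested members were higher and 0 lower. There, 74.8% of windows of as many neighbouring features had a lower SD of log2 changes. This is over the bound set as the mark of a single factor and under the 95% set as arguing against it. That bound was the middle of the windows, which many windows without a common factor meet by construction. A share under it therefore does not show a single factor. The share was 49.8% for the interaction and 83.1% for kaiA-Ex/labA-KO vs kaiA-Ex. It was also low, at 52.6%, for kaiA-Ex/labA-KO vs labA-KO, where the median log2 change of these rows was only -0.08. It was 89.0% for labA-KO vs WT and 89.1% for kaiA-Ex/labA-KO vs WT, and none reached 95%. The SD does not show direction. In labA-KO vs WT 35 members were lower and 8 higher, and in kaiA-Ex/labA-KO vs WT 36 and 10. Such moves both ways argue against a single factor alone in these contrasts. A regulated response of these features to the strain changes was not tested.

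Fewer features were called for kaiA overexpression with zinc in the labA-KO background than in WT. Depth is argued against, since the ratio of the 2 counts stayed at 2.57 after thinning to the lowest total. A larger spread between replicates is argued against as the whole cause, since the variance of the log2 changes, less their mean squared SE, was 2.15 times as large in the WT background. These SE came from the fit of all libraries and do not measure the spread of each background. The median SD of log2 CPM within a group was 0.064 in WT, 0.084 in kaiA-Ex, 0.074 in labA-KO and 0.110 in kaiA-Ex/labA-KO. With only the libraries compared in each fit, 1592 and 313 features were called, so spread may be part of the cause. An effect of the labA knock-out on the response stays open and was not tested apart from the interaction that drew attention to it, and zinc cannot be separated from kaiA.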

How the results depend on the processing

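The thinned libraries, the outlying pair, the features with a range over 20-fold, the rows listed first, the block fit of 6 libraries, and the settings tried for agreement, runs and those rows were chosen only after the data were seen. The counts of calls were within 1.5 times the main value under 129 alternatives, and moved under 9. A fold threshold of log2 1 asks for larger changes by construction and left 112 features for kaiA-Ex vs WT, 109 for labA-KO vs WT, 149 for kaiA-Ex/labA-KO vs WT, 142 for kaiA-Ex/labA-KO vs kaiA-Ex, 10 for kaiA-Ex/labA-KO vs labA-KO and 38 for the interaction. The last pairwise contrast fell to 314 at an adjusted p under 0.01, and to 313 with only the libraries compared, a fit of fewer samples. Of the named features' values, each in the contrast it was named for and in a called interaction, 818 were on the same side of the threshold and 24 were not. Calls were lost under the fold threshold, and also for gene-SYNPCC7942_RS05255 at the stricter p and, in its interaction, without single libraries or the outlying pair, and for gene-SYNPCC7942_RS13855 at the stricter p and with limma-voom. Assembled transcript B changed sign in labA-KO vs WT, where it was not called (-0.17 to 0.29 with a library left out). No value of the named features, of transcript A, of the agreement of contrasts or of the median of the rows listed first changed sign. The median log2 change of all features lies near 0 and could change sign. In kaiA-Ex vs WT it went from 0.002 to -0.040 with upper-quartile factors. The median of the rows listed first moved beyond its jackknife SE under 10 alternatives and not under 110, and the number of features in runs moved by over 1.5 times under 22 and not under 116. gene-SYNPCC7942_RS13855 had no value with the strict filter or without the features with a range over 20-fold.

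Leaving out each library in turn gave r between 0.18 and 0.39 for kaiA overexpression in both backgrounds, the lowest without kaiA-Ex replicate 2, and between 0.56 and 0.61 for the knock-out in both backgrounds. The latter was 0.70 with the strict filter, 0.65 without features with a range over 20-fold, and 0.67 among features called in at least 1 of the pair; the cause was not tested. Their jackknife SE was 0.179 and 0.0430. Without kaiA-Ex replicate 2 and kaiA-Ex/labA-KO replicate 1 together, r was 0.25.

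In the other 4 pairwise contrasts the replicate numbers were not taken to pair the samples. Over all groups, deviations of same-numbered libraries correlated above 0.1 in 4 of 18 pairs, from -0.39 to 0.44. Of 12 libraries, 3 correlated best with a library of their own number. With the replicate block the calls were 1485, 1371, 1600, 1345, 514 and 942, in the order of the contrasts above. In kaiA-Ex/labA-KO vs labA-KO, where the numbers were taken to pair the libraries, the block in a fit of these 6 libraries left 283 calls. Under either block fit none of the 4 features named for this contrast lost its call. Tests of the gene lists, the target genes, and agreement without the kai and lab genes were not run, since IDs could not be matched to names. Features at 1 to 3 counts are limited by depth.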

Other observations

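The alternatives for the assembled transcripts were added after the data were seen. The tests of random drop-outs and of a lost locus were chosen only after gene-SYNPCC7942_RS06270 was singled out by its values. It had 2 to 3 counts in each kaiA-Ex library, and 12.2 ± 0.624 CPM in WT, 16.1 ± 0.537 in labA-KO and 10.8 ± 3.18 in kaiA-Ex/labA-KO (SD, n = 3). The ratio of its depth-scaled counts, WT (2851 in all) over kaiA-Ex (8 in all), was 394.8 (95% exact Poisson interval 200.1 to 915.4, counting error only). It was the 1 feature with at most 5 counts throughout kaiA-Ex and at least 100 in all other libraries. Random drop-outs of the estimate stay open: over the 2 features with exactly 3 drop-outs, of 8 with any, the chance that any had all in 1 group was 0.036, but the feature was picked for that very placing, so this decides nothing. A short loss or rearrangement at the locus in the kaiA-Ex strain may explain it and stays open too, since the adjoining features changed by at most 0.35 on the log2 scale, which a short loss allows.

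In 36 features, CPM ranged over 20-fold within a group. The assembled transcripts without a locus tag, A and B, rose in kaiA-Ex vs WT by log2 changes of 2.22 (SE 0.19) and 1.63 (SE 0.24). Transcript A was itself among the rows listed first, so its changes are not a separate result from theirs. Transcript A was lower in labA-KO vs WT, at -0.78 (SE 0.18), and in kaiA-Ex/labA-KO vs WT, at -0.91 (SE 0.18), and its interaction was -2.35 (SE 0.26). Transcript B was at 0.09 (SE 0.23) in labA-KO vs WT, which did not pass the test, and rose by 0.84 (SE 0.23) in kaiA-Ex/labA-KO vs WT; its interaction of -0.88 (SE 0.33) did not pass the test (adjusted p 0.0558 in edgeR's quasi-likelihood test) but passed it under 6 alternatives. Deviations of kaiA-Ex replicate 2 and kaiA-Ex/labA-KO replicate 1 from their group means correlated at 0.53 across features.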
